A study of Mus musculus with 8 samples.

How the data were processed

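RNA was measured on Affymetrix gene arrays, 1 array per sample, in 8 mouse samples. Of these, 6 were sperm from the caudal epididymis (3 control diet, 2 low protein diet, 1 caloric restriction) and 2 were epididymal tissue (1 control diet, 1 low protein diet). The deposited values are log2 intensities, 1 per probe set and array, and they were made with RMA per the submitters' processing notes. RMA, as usually run, corrects background, quantile-normalizes the probes and summarizes them per probe set. Its version and the annotation used with it are not given in the sources used here. The log2 scale was read from the deposited values, which run from about 1.2 to 14.5, and the median over all probe sets lay between 6.08 and 6.17 on the 8 arrays. Where quantile normalization gives every array nearly one distribution, a change in total RNA per cell is not visible, and a rise in some genes lowers others.

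The table held 33660 probe sets. By the platform annotation, 21222 carried 1 gene, 1541 carried several and 10897 were unnamed here. Symbols were updated through the gene identifier with an annotation of assembly GRCm38 for 21137 of the named probe sets, and 85 kept the platform's symbol. That annotation was used only for names, since the build behind the files is not given in the sources used here, and no coordinates are printed. The probe set with the highest mean stood for a gene, which gave 19411 genes. The lowest 30% by mean over all arrays were left out (log2 5.69 and below), and 13587 genes were tested.

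Tests used limma 3.58.1 in R 4.3.3, with lmFit and eBayes, two-sided, and Benjamini-Hochberg adjustment over the 13587 genes at a threshold of 0.05. Errors of log2 changes are moderated standard errors from that fit. The sperm diet comparisons used the 6 sperm arrays with a mean per diet. The single caloric restriction array was assumed to vary like the other sperm groups. A further fit set the 3 restricted diet arrays against the 3 control arrays. Sperm and epididymis were compared over 8 arrays with tissue and diet as additive terms; the caloric restriction array has a diet term of its own there, so 5 sperm and 2 epididymis arrays set the tissue effect. The difference between the diet effects in the 2 tissues used the same 8 arrays with a mean per group. The epididymis diet comparison had 1 array per group and no test; list medians there are given as percentiles among 10000 random lists of the same size matched on mean expression in 20 bins. The number of arrays limits the precision.

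Before the data were examined, 28 gene lists were fixed (15 of cell type markers and 13 of pathways). They were tested with camera at a preset correlation between genes of 0.01, adjusted over the 28 lists, and again with a correlation estimated per list. No list call in any comparison held with an estimated correlation. That test also failed for the sperm tail list between sperm and epididymis, where all 34 genes rose (estimated correlation 0.80, adjusted p by camera 0.419). Failing it therefore cannot tell a list that changed from one that did not. A rule for the genes named in the text was fixed at the same time. It took up to 12 of the largest rises and 12 of the largest falls among genes past the threshold whose group values did not overlap. Where fewer than 12 passed in a direction, genes of smallest p filled up to 8 and are named as not past the threshold. The rule added up to 3 members of each list with the largest change, and Actb, Myh11, Smarcd3 and Ppard. In the epididymis diet comparison it took the 12 largest differences each way among genes above the median level. Which of these list members are named, and which examples are given with values, was chosen after the values were seen.

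The labels do not state that replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical. No 2 arrays held the same values, and the pairwise correlation over tested genes within sperm ran from 0.71 to 0.98.

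Each fit was tested on simulated arrays of the 13587 genes with known changes. The simulated noise was normal and independent between genes and arrays, with the fitted spread of each gene. It held no correlation between genes and no outlying array such as low protein replicate 2. The shares below may therefore not hold for the real arrays. For low protein against control in sperm, 83.6% of genes changed by 1 on the log2 scale were recovered. For caloric restriction against control the share was 35.8%, for the restricted diets together 95.5%, for low protein against caloric restriction 34.3%, and for sperm against epididymis 92.5%. For the difference between tissues in the diet effect it was 0, and 77.3% at a change of 2.

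The alternatives tried were other normalizations between arrays (median centring, quantile normalization, cyclic loess), no filter and a 50% filter, the mean of a gene's probe sets, eBayes with a trend or robust, other thresholds, a marker-based covariate, other sets of samples and models, and leaving out each array. The covariate was the mean level of the epithelium, smooth muscle and fibroblast and matrix lists on an array. It was 7.85 to 7.92 on control sperm arrays, 7.61 and 7.25 on low protein and 7.65 on caloric restriction arrays. Because it separates the diets, signs and counts under it cannot tell composition from diet. One alternative, sperm against epididymis without low protein replicate 2 and caloric restriction, was chosen after seeing the data.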

Results

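The series asked how control, low protein and caloric restriction diets of male mice relate to the RNA in their sperm. Males of the control and low protein groups were raised on their diet to 9 to 12 weeks of age. No age is stated for the caloric restriction group, nor whether its sample was handled with the others, so age and handling cannot be told apart from that diet. Sperm preparations were more than 99.5% pure by microscopy, per the labels, and preparations with detectable Actb or Myh11, transcripts of the surrounding tissue, had been rejected by PCR. The sperm arrays nevertheless held signal of Actb and of epididymal markers, as given below. There were 3 control, 2 low protein and 1 caloric restriction sperm arrays, and 1 epididymis array for each of control and low protein.

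Sperm had higher levels than epididymis of transcripts of late spermatids and lower levels of those of muscle and matrix. Gtsf1, a piRNA pathway gene, rose by 5.09 ± 0.27 (SE; 5 sperm and 2 epididymis arrays, as the caloric restriction array has a diet term of its own and adds nothing to the tissue effect) on the log2 scale. The transition protein gene Tnp2 rose by 4.50 ± 0.28 and the protamine gene Prm1, whose product packs sperm DNA, by 4.06 ± 0.27. Gapdhs, a sperm glycolytic enzyme, rose by 4.06 ± 0.20 and the sperm protein gene Crisp2 by 3.84 ± 0.20. The smooth muscle myosin gene Myh11 fell by 4.10 ± 0.20 and the muscle actin gene Acta2 fell by 3.90 ± 0.51. Cnn1 fell by 3.56 ± 0.17 and the basal cell keratin gene Krt5 fell by 2.23 ± 0.14.

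Of 13587 genes, 6594 passed, 2501 higher and 4093 lower in sperm, and 37.9% of the calls were higher. After cyclic loess, which moved the median change of all genes from -0.08 to 0.06, the share was 52.7%. Other large rises were those of Itpr3os, Mroh5, Phospho1, Fabp9, Dbil5, 1700012A03Rik, Spem1, Spz1, Iqcf4 and Spem2, between 4.17 and 4.80, and other large falls those of Sparcl1, Cpe, Timp3, Cald1, Pgm5, Des, Igfbp7 and Slc24a3, between -3.89 and -3.14. All 34 sperm tail genes and all 23 acrosome genes tested rose, as did 11 of 13 chromatin packaging genes; adjusted over the list alone the counts were 34, 23 and 11. Of 16 smooth muscle genes 15 fell (16 adjusted over the list alone), of 37 epididymal epithelium genes 25 fell and 2 rose (27 and 2 adjusted over the list alone), and of 20 cholesterol synthesis genes 17 fell and 1 rose (17 and 1 adjusted over the list alone). Camera called 16 of 28 lists, 7 up and 9 down, and none held (smallest adjusted p = 0.419 with an estimated correlation). Actb fell by 1.44 ± 0.20. Its levels in control and low protein epididymis were 12.7 and 12.5, so it stayed a bright signal in sperm despite the PCR screen described above. Smarcd3 differed by -0.35 ± 0.53 (adjusted p by limma 0.606, with differences of 0.26 after quantile normalization and 0.51 after cyclic loess) and Ppard by 0.49 ± 0.23 (adjusted p by limma 0.108). Without the low protein epididymis array the count was 2748.

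Markers of epididymal tissue were also measured in sperm. For the 19 epithelium markers brighter than log2 9 in epididymis, a level chosen after the values were seen, the median signal was 50.4% ± 6.78 (SD, n = 3) of the epididymis in control sperm, 27.1% ± 13.6 (SD, n = 2) in low protein sperm and 32.5% in caloric restriction sperm. For 13 smooth muscle markers it was 16.7% ± 1.19 (SD, n = 3), 8.84% ± 2.45 (SD, n = 2) and 12.9%. For 7 fibroblast and matrix markers it was 38.0% ± 12.7 (SD, n = 3), 36.4% ± 8.85 (SD, n = 2) and 46.6%.

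**Figure D1:**
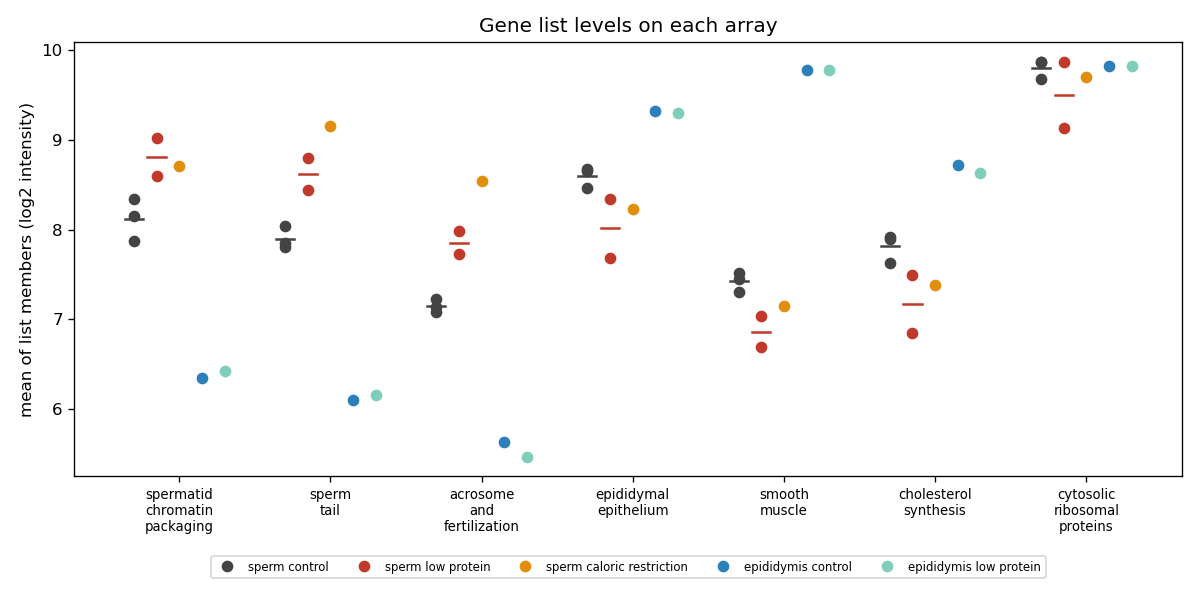
Mean log2 intensity of the members of 7 gene lists (horizontal axis) on each of the 8 arrays, with 1 point per array and a bar at the mean of a group with over 1 array. The acrosome list lies between 7.08 and 7.23 on the control sperm arrays, at 7.73 and 7.98 on the low protein arrays and at 8.54 on the caloric restriction array.

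In low protein sperm, no single gene passed the test against control, while germ cell lists had higher and epididymal and sterol lists lower values. The actin capping gene Capza3 differed by 1.17 ± 0.17 (SE; 2 low protein and 3 control arrays), the axonemal gene Spag17 by 1.10 ± 0.21, the soluble adenylyl cyclase Adcy10, needed for sperm motility, by 1.15 ± 0.21, and the tail fiber gene Odf4 by 1.06 ± 0.17. Acta2 differed by -1.81 ± 0.45, the stearoyl-CoA desaturase gene Scd2 by -1.51 ± 0.36, and the sterol synthesis genes Nsdhl and Idi1 by -1.12 ± 0.39 and -1.08 ± 0.34. None of these was past the threshold. With the marker mean as a covariate the signs of these 4 genes turned (Acta2 0.41, Scd2 0.17, Nsdhl 0.81 and Idi1 0.50). That mean is made of epididymal, muscle and fibroblast marker levels. It did not overlap between control (7.85 to 7.92) and low protein arrays (7.61 and 7.25), so the turn cannot tell composition from diet.

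Limma with eBayes called 0 of 13587 genes (smallest adjusted p 0.0847), as did eBayes with a trend and robust eBayes. By limma 3406 genes had an unadjusted p under 0.05, 1622 higher and 1784 lower. At an adjusted p under 0.10 by limma there were 592, 559 higher and 33 lower. Also not past the threshold were Ccdc192, Fscn3, Rimklb, Lrrc74a, Lrrc9, D7Ertd443e and Dnah7c, between 1.08 and 1.16, and Csrp1, Cd1d1, Abcc3, Tagln, Clu, Slc23a1, Them4 and Scamp5, between -1.32 and -0.77. Camera called 15 lists. Those up included the sperm tail list (median 0.71), acrosome (0.76), chromatin packaging (0.77) and earlier germ cells (0.68); those down included cholesterol synthesis (-0.71), epididymal epithelium (-0.66), fatty acid synthesis (-0.63), ribosomal proteins (-0.40) and smooth muscle (-0.39). Low protein replicate 2 carried much of the lower values in several of the lists called down: without it the medians were -0.37 for cholesterol synthesis, -0.27 for epididymal epithelium, -0.29 for fatty acid synthesis, 0.0759 for ribosomal proteins and -0.08 for chromatin regulators (-0.20 with all arrays). Without replicate 1 the last 3 were -1.03, -0.85 and -0.40. None of the 15 calls held (smallest adjusted p = 0.482 with an estimated correlation). Adjusted over the list alone, 27 of 34 sperm tail genes, 17 of 23 acrosome genes and 10 of 13 chromatin packaging genes were higher, and 14 of 20 cholesterol synthesis genes and 8 of 37 epithelium genes lower (2 epithelium genes were higher), against 0 over all genes tested. In the same arrays the epithelium marker signal was 36.7% and 17.5% of the epididymis, against 42.6% to 54.6% in control sperm. The fibroblast and matrix (-0.15) and endothelium (0.03) lists were not called, and the leukocyte list was called up (0.23, adjusted p = 0.679 with an estimated correlation; 0.06 without control replicate 2 and 0.13 without low protein replicate 2). Actb differed by -0.73 ± 0.20, Myh11 by -0.71 ± 0.19, Smarcd3, a subunit of the SWI/SNF remodeller, by -1.33 ± 0.53, and Ppard, a lipid-sensing nuclear receptor, by -0.75 ± 0.24, all short of the threshold; with the covariate Smarcd3 was 1.47 and Ppard 0.13. Low protein replicate 2 lay apart, with a correlation of 0.71 to 0.86 with the other sperm arrays over the tested genes: Smarcd3 was 8.05 there and 10.2 in replicate 1. Without low protein replicate 1 the count was 5155, with the lone array assumed to vary like the control group.

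In the single caloric restriction sperm array, sperm tail, acrosome and ion channel genes rose against control. Fsip2, a fibrous sheath gene, rose by 2.90 ± 0.28 (SE; 1 caloric restriction and 3 control arrays), the androglobin gene Adgb by 2.86 ± 0.20, the sperm calcium channel genes Catsper3 and Catsper4 by 2.48 ± 0.22 and 2.28 ± 0.21, and Izumo1, required for sperm-egg fusion, by 2.40 ± 0.21. The deubiquitinase gene Usp17ld fell by 2.47 ± 0.30 and the epididymal glutathione peroxidase gene Gpx5 fell by 1.42 ± 0.21. The lipocalin gene Lcn2 fell by 1.18 ± 0.20, Lce6a fell by 1.11 ± 0.20 and the matrix gene Bgn fell by 1.01 ± 0.23.

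Limma called 756 genes, 751 higher and 5 lower, with a median size of 1.36 on the log2 scale; at an unadjusted p under 0.05 there were 1688 higher and 567 lower. The spread behind these calls came from the control and low protein arrays, since a single array has none, and the values describe that array. The other large rises were Speer3, Lrriq1, Dcdc2c, AA467197, 1700028P14Rik, Enkur, Dydc1, Zdhhc11 and Spaca7, between 2.50 and 2.83. Ctla2a, Gm13375 and Spink14 differed by -0.90, -0.99 and -2.51 and were not past the threshold. Of 34 sperm tail genes 22 rose (30 adjusted over the list alone), of 23 acrosome genes 15 (21 adjusted over the list alone), of 18 glycolysis and energy genes 10 (13 adjusted over the list alone) and of 13 chromatin packaging genes 2 (2 adjusted over the list alone). The list medians were 1.32, 1.35, 1.14 and 0.51. Among 14 earlier germ cell genes 6 rose (7 adjusted over the list alone) and among 12 ion transport genes 6 (9 adjusted over the list alone). Of 37 epididymal epithelium genes 2 rose and 1 fell (2 and 1 adjusted over the list alone), and the epithelium marker signal was 32.5% of the epididymis in this array. The piRNA pathway genes Tdrd6 and Mael rose by 2.07 ± 0.22 and 2.02 ± 0.24, and the germ cell variants Cox8c and Rpl39l of respiratory and ribosomal proteins by 1.73 ± 0.23 and 1.67 ± 0.26. Camera called 11 lists, 7 up and 4 down, and none held (smallest adjusted p = 0.431 with an estimated correlation). Actb, Myh11, Smarcd3 and Ppard differed by -0.22 ± 0.25, -0.17 ± 0.23, -0.67 ± 0.67 and -0.98 ± 0.30, none past the threshold; with the covariate the signs of Actb (0.13), Myh11 (0.083) and Smarcd3 (0.75) turned. The count was 1757 with the marker covariate (1289 higher and 468 lower) and 2021 (1519 higher and 502 lower) when either low protein array was left out, the latter since the spread then came from the controls alone. It was 487, 298 and 326 without control replicate 1, 2 and 3.

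**Figure D2:**
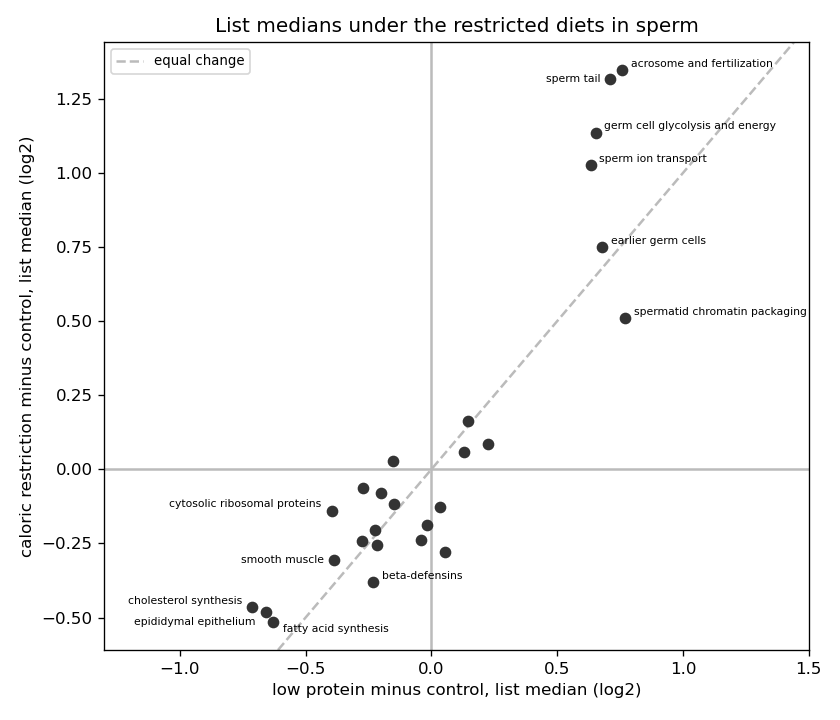
Median log2 change of each list with over 2 tested members, for low protein minus control (horizontal axis) and caloric restriction minus control (vertical axis) in sperm, with 1 point per list and a dashed line at equal change; lists with small changes on both axes carry no name. The acrosome list lies at 0.76 and 1.35, and the chromatin packaging list at 0.77 and 0.51.

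Changes under both diets were correlated across genes. Over 13587 genes, which are not independent replicates, Pearson's r was 0.68 and Spearman's rho 0.66, and 72.9% of genes had the same sign. Unchanged groups simulated 100 times against shared controls gave 0.32, 0.30 and 60.2%. The simulated genes were independent of each other, which real genes are not, so the draws do not give the range that correlated genes would allow. The covariance was 0.156, against 0.0178 simulated, a difference of 0.138. The epithelium marker signal was lower under both diets (50.4% of the epididymis in control, 27.1% in low protein and 32.5% in caloric restriction sperm), as was that of smooth muscle (16.7%, 8.84% and 12.9%), while that of fibroblast and matrix was not lower under both (38.0%, 36.4% and 46.6%). The simulated values already hold the part that shared controls give when genes are independent. With 3 controls, a split into parts of at least 2 arrays was not possible. Whether errors common to the control arrays add to the excess was therefore not tested.

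Between low protein and caloric restriction sperm, no gene passed. Usp17ld differed by 3.10 ± 0.31 (SE; 2 low protein and 1 caloric restriction arrays), Gpx5 by 1.39 ± 0.22, Speer3 by -2.43 ± 0.27, Adgb by -2.02 ± 0.22, Catsper3 by -1.86 ± 0.23 and Izumo1 by -1.69 ± 0.22. Limma called 0 genes (smallest adjusted p 0.0646); 1316 had an unadjusted p under 0.05, eBayes with a trend called 23 and robust eBayes 0. Also short of the threshold were Fut11, Macrod2, Mtag2, Ctla2a, Prrg4 and Lcn2, between 0.96 and 1.68, and Zdhhc11, Spag6, Lrriq1, Efcab9 and Spaca7, between -1.89 and -1.58. Camera called 6 lists, all with lower values under low protein, among them acrosome (median -0.67) and sperm tail (-0.50); none held (smallest adjusted p = 0.822 with an estimated correlation). Without either low protein replicate this comparison sets 1 array against 1, with all spread from the controls. Counts from such fits describe 2 single arrays and do not measure a difference between the diets.

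With both restricted diets together against control, germ cell genes rose. The axonemal dynein gene Dnah7a rose by 1.51 ± 0.28 (SE; 3 restricted and 3 control arrays), Spag17 by 1.24 ± 0.20, Adcy10 by 1.23 ± 0.19, the germ cell helicase gene Ddx4 by 1.31 ± 0.25 and the testis bromodomain gene Brdt by 1.01 ± 0.22. Stxbp3 fell by 0.88 ± 0.19, Lce6a fell by 0.84 ± 0.17, Adgrf5 fell by 0.79 ± 0.17 and Scamp5 fell by 0.73 ± 0.15.

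Limma called 373 genes, 369 higher and 4 lower, with smallest adjusted p 0.0411. At an unadjusted p under 0.05 there were 1695 higher and 1897 lower, and at an adjusted p under 0.10 there were 910 higher and 181 lower. The largest rises also included Dcdc2c, Ccdc192, Tmco5, Iqub, A26c3, Rimklb, Gm1698, Fam71e2, Ms4a5, Efhb and Fbxl13, between 1.40 and 1.72; Gnl3l, Atp6v0d2, Ogfod3 and Tbc1d8b differed by -0.88 to -0.69 and were not past the threshold. Of 34 sperm tail genes 13 rose (31 adjusted over the list alone) and of 23 acrosome genes 6 (19 adjusted over the list alone). Of 20 cholesterol synthesis genes 0 fell by limma, and 15 adjusted over the list alone. Camera called 16 lists, 8 up and 8 down, and none held (smallest adjusted p = 0.385 with an estimated correlation). The sperm tail level was 0.90 higher in the restricted arrays and the epithelium level differed by -0.51, each with exact two-sided permutation p = 0.10, the smallest that 3 against 3 arrays allow. The median change of the epithelium list was -0.62, and -0.40 without low protein replicate 2. Actb, Myh11, Smarcd3 and Ppard differed by -0.56, -0.53, -1.11 and -0.82, none past the threshold; with the covariate the signs of Actb (0.12), Myh11 (0.057) and Smarcd3 (0.81) turned. The epithelium marker signal of the restricted arrays was 36.7%, 17.5% and 32.5% of the epididymis. The count was 0 with the marker covariate, and 0 without any 1 of the 3 control arrays or the caloric restriction array, and it was 1428 (958 higher and 470 lower) without low protein replicate 1 and 654 (627 higher and 27 lower) without replicate 2. The covariate ran from 7.85 to 7.92 on the control and from 7.25 to 7.65 on the restricted arrays. With no overlap, the 0 under it cannot tell composition from diet.

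**Figure D3:**
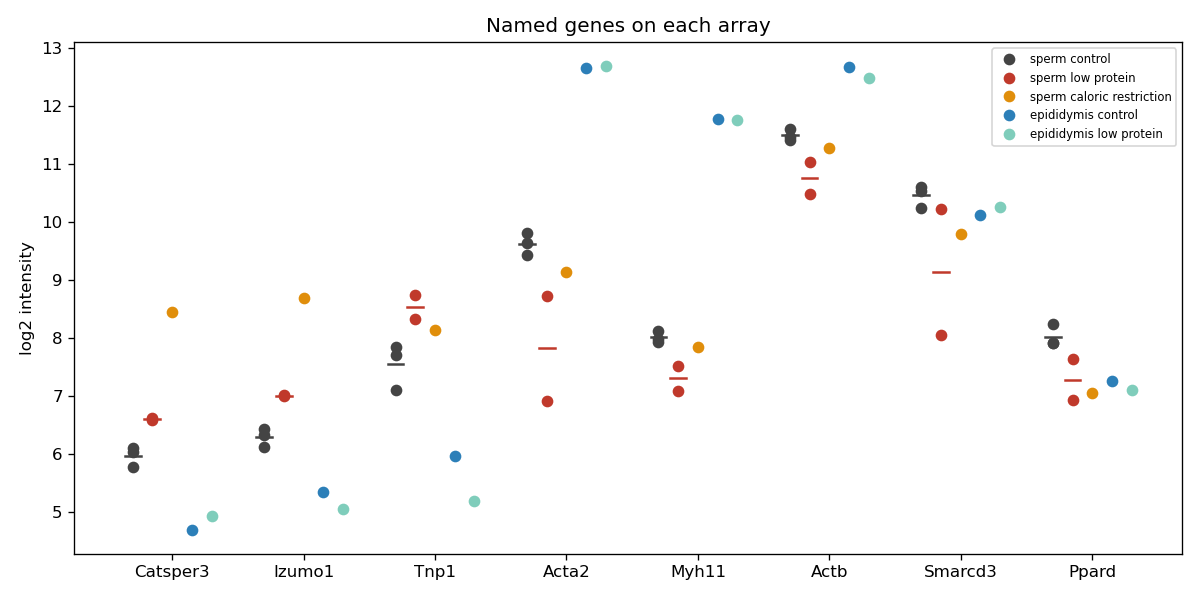
Log2 intensity of 8 named genes (horizontal axis) on each of the 8 arrays, with 1 point per array and a bar at the mean of a group with over 1 array. Catsper3 lies at 8.46 on the caloric restriction array and at 6.58 and 6.61 on the low protein arrays, and Smarcd3 at 8.05 on low protein replicate 2.

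Low protein and control epididymis, with 1 array each and no test, could not be set against a spread between replicates. The SD of the differences over 13587 genes was 0.19, and 9 genes differed by at least 1, 1 higher and 8 lower under low protein. By the fixed rule the lowest were the complement genes C4bp (-1.56) and C7 (-0.86), Glb1l3 (-1.39), Wfdc13, Bmi1 (-0.86), Smim27 (-0.79), the lysozyme gene Lyz2 (-0.79), Defb42 (-0.76), Laptm5 (-0.76), Lce6a (-0.71), Ramp3 (-0.69) and Trf (-0.67). The highest were Lgalsl (1.10), AI506816 (0.95), the amylase gene Amy1 (0.79), Ormdl2 (0.73), Arl1 (0.69), Ndufaf4 (0.67), 4930453N24Rik (0.63), Nme3 (0.61), Daam1 (0.56), 4930451I11Rik (0.55), Macrod2 (0.54) and Rangrf (0.53). The leukocyte list had a median difference of -0.38 and the fibroblast and matrix list of -0.23, each at percentile 0 of 10000 random lists. Random lists do not allow for members that move together, so a percentile is not a p-value. In the fit of sperm against epididymis the estimated correlation was 0.66 for leukocytes and 0.045 for fibroblast and matrix. The cholesterol synthesis list (-0.13) lay at percentile 0.05, the acrosome list (-0.16) at 0.07 and the proteasome (-0.11) at 0.13. Ion transport (0.19) lay at 98.9 and chromatin packaging (0.12) at 96.8, and the other lists between 3.42 and 85.4. The acrosome levels in epididymis, 5.64 and 5.47, lay under the filter limit of 5.69, and those of ion transport, 5.67 and 5.79, lay close to it. The number of genes differing by at least 1 was 24 without the filter and 5 with the 50% filter.

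The low protein effect in sperm was compared with that in epididymis. Car4, a carbonic anhydrase gene, differed between the effects by 2.20 ± 0.40 (SE; 2 and 3 sperm and 1 and 1 epididymis arrays), Nlrp5-ps by 2.00 ± 0.42, Mlf1 by 1.92 ± 0.35, Adgb by 1.64 ± 0.30 and the muscle gene Tagln by -1.14 ± 0.38, none past the threshold. Limma called 0 genes (smallest adjusted p 0.875), as did eBayes with a trend and robust eBayes; 610 had an unadjusted p under 0.05. Also short of the threshold were Erich6, Rnf19b, Efcab9 and C4bp, between 1.36 and 1.63, and Cks1brt, Adgrf5, Slc23a1, Tmem126a, Arl1, Syngr2 and Magee1, between -1.08 and -0.89. In control and low protein epididymis Adgb (5.10 and 4.30), Erich6 (4.69 and 4.02) and Efcab9 (5.14 and 4.53) lay under the filter limit of 5.69, and Car4, Nlrp5-ps, Mlf1 and Cks1brt did on 1 of the 2 arrays, so these differences rest partly on dim values. Camera called 15 lists, and none held (smallest adjusted p = 0.489 with an estimated correlation). Across genes the 2 effects had a Pearson's r of 0.07 and a Spearman's rho of 0.07. The epididymis effect was 1 array minus 1 array, with an SD of 0.19 over genes. Differences between pairs of control sperm arrays had SDs of 0.22 to 0.31. So low a correlation therefore cannot tell unrelated effects from noise in the epididymis arrays. Without low protein sperm replicate 1 every group but control sperm held 1 array, so calls from that fit do not measure a difference between the diet effects.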

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

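All the weighing tests in this part were chosen after the results were seen; the list tests of the difference between tissues had been planned. The diet effect of 15 lists differed between sperm and epididymis by camera at the preset correlation, and none did with an estimated one. The median differences, sperm effect minus epididymis effect, were 0.95 for acrosome, 0.77 for germ cell glycolysis, 0.69 for earlier germ cells, 0.65 for sperm tail, 0.59 for leukocytes, 0.53 for chromatin packaging, 0.48 for ion transport and 0.17 for the piRNA pathway. They were -0.65 for cholesterol synthesis, -0.50 for smooth muscle, -0.47 for epididymal epithelium, -0.45 for fatty acid synthesis, -0.43 for ribosomal proteins, -0.29 for insulin and fasting signalling and -0.24 for chromatin regulators. The acrosome levels in epididymis, 5.64 and 5.47, and those of earlier germ cells, 5.46 and 5.36, lay under the filter limit of 5.69. Ion transport, at 5.67 and 5.79, lay close to it. The differences of these lists in epididymis are thus ones of dim genes. Without low protein replicate 2 the medians were -0.26 for cholesterol synthesis, -0.22 for epididymal epithelium, -0.27 for fatty acid synthesis, 0.0463 for ribosomal proteins, -0.11 for chromatin regulators, 0.31 for chromatin packaging and 0.11 for the piRNA pathway. Without replicate 1 they were -0.97, -0.83, -0.86, -0.84 and -0.40 for the first 5 of these. Chromatin packaging was 0.34 without control replicate 3 and leukocytes 0.36 without control replicate 2. Of the 1541 probe sets with several genes and the 10897 unnamed ones, 6014 had a mean above the filter limit of 5.69 and were tested apart. Among 6014 probe sets with several genes or none, which the comparisons left out, 208 passed for caloric restriction against control (201 higher) and 1820 for sperm against epididymis (696 higher).

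Germ cell lists were higher and epididymal lists lower in low protein sperm. The epithelium list was lower largely in replicate 2 (median -0.27 without it) and smooth muscle in both (levels of 7.04 and 6.69 against 7.43 in control). The sperm tail median was 0.74 after cyclic loess and 0.71 as deposited, which argues against a difference between the deposited arrays that loess removes. Cyclic loess cannot undo the normalization within RMA, so that stays untested. Less epididymal RNA in the 2 low protein preparations stays open as a candidate explanation. Across genes, which are not independent, the effect correlated with caloric restriction sperm minus epididymis at r = 0.76 and rho = 0.72. The caloric restriction array is itself of a restricted diet, so a change shared by both diets would give such a correlation too. The correlation therefore cannot tell less epididymal RNA from a diet effect. Of the epithelium, fibroblast and beta-defensin lists, the one farthest from smooth muscle, fibroblast and matrix, differed from it by 0.34 ± 0.21 (SE between arrays), in a test that was widened from 1 list to 3 after the values were seen. Endothelium cannot decide on less epididymal RNA. Its low protein arrays, at 5.94 and 6.33, lay on either side of the control arrays (6.08 to 6.25). The endothelium list was 0.44 higher in epididymis than in control sperm but not called between the tissues. It changed by -1.78e-04 ± 0.16 and differed from smooth muscle by 0.56 ± 0.28, while fibroblast and matrix changed by -0.22 ± 0.11. The 7 bright fibroblast and matrix markers cannot decide either, at 38.0% ± 12.7 (SD, n = 3) of the epididymis in control and 36.4% ± 8.85 (SD, n = 2) in low protein sperm. Control arrays alone ran from 29.6% to 52.5%, which spans the low protein arrays at 42.6% and 30.1%. Bright epithelium markers went from 50.4% to 27.1% and smooth muscle from 16.7% to 8.84%. A diet effect within sperm, which the design names, also stays open and was not separately tested.

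Genes were higher in the caloric restriction array. Less epididymal RNA alone would raise sperm lists alike, but the acrosome minus chromatin packaging difference exceeded that in low protein sperm by 0.78 ± 0.23 (SE from the spread of control and low protein arrays only, as caloric restriction had 1 array). Compression of bright probe sets is argued against, since that difference was 0.0207 in low protein sperm and 0.80 in caloric restriction sperm. More RNA of earlier germ cells cannot be told apart from a diet effect: the earlier germ cell median was 0.75, above 0 and below the acrosome median of 1.35, and there was 1 array. The diet itself stays open, untested, as do age and handling, which are not stated for this sample.

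Low protein replicate 2 lay apart from the other sperm arrays. Among 1836 genes at like levels in control sperm and epididymis (within 0.25, and above the median level; both limits were set after the values were seen), where less epididymal RNA should change little, 11.4% differed by at least 1 from the control mean on that array, 11.3% lower and 0.109% higher. The share was at most 0.109% on a control array against the other controls, 0 on low protein replicate 1 and 1.69% on the caloric restriction array, which argues against less epididymal RNA as the whole cause. After cyclic loess the share on low protein replicate 2 was 8.66%. That argues against a difference between the deposited arrays that loess removes as the whole cause. The normalization within RMA could not be tested in this way. RNA quality was not tested, and the low protein diet stays open, though replicate 1 of that diet did not share the pattern.

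For the restricted diets against control, the 6 sperm arrays allow 10 splits, too few for a share under 0.05. The real split gave 373 genes, 1 of the 10 splits gave as many, and the highest of the others gave 0.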

How the results depend on the processing

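The cause was not tested unless stated, and sperm against epididymis without low protein replicate 2 and caloric restriction was chosen after seeing the data. No paired analysis was possible because the labels give each sample a letter of its own, with no number shared between groups. Median centring, quantile normalization, cyclic loess, the mean of probe sets and robust eBayes kept all 6 tested counts within 1.5 times. At adjusted p under 0.10, low protein against control gave 592 genes, low protein against caloric restriction 131 and the restricted diets 1091. With a log2 change of at least 1, the restricted diets gave 192 and the tissues 2999. The trend gave 23 for low protein against caloric restriction and 168 for the restricted diets, for which the 50% filter, with fewer genes tested, gave 197. In epididymis that filter gave 5 and no filter 24. Control and caloric restriction sperm alone gave 2021. With the marker covariate, caloric restriction gave 1757, low protein against caloric restriction 630 and the restricted diets 0. With an estimated correlation, 0 lists were called in each of the 6 comparisons; without the filter, 11 lists differed between low protein and caloric restriction.

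The marker covariate holds the levels of the epithelium, smooth muscle and fibroblast lists, so members of those lists are adjusted by their own mean. It does not overlap between control and restricted sperm arrays, so a turn of sign under it cannot tell composition from diet. With this covariate the following changes turned positive. In low protein sperm they were Acta2 0.41, Adam7 0.80, Lcn12 0.96, Spink8 0.50, Nsdhl 0.81, Idi1 0.50, Scd2 0.17, Fads2 0.69, Hdac6 1.23, Shmt2 1.05, Smarcd3 1.47 and Ppard 0.13. In caloric restriction they were Actb 0.13, Myh11 0.083 and Smarcd3 0.75, and in the restricted diets Acta2 0.62, Actb 0.12, Myh11 0.057 and Smarcd3 0.81. Smarcd3 between low protein and caloric restriction was 0.72. Between tissues Smarcd3 was 0.26 after quantile normalization, 0.51 after cyclic loess, 0.35 on control diet and 0.19 without low protein replicate 2 and caloric restriction. Actb in the difference of diet effects was 0.27 after cyclic loess.

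Leaving out 1 array at a time gave 0 to 5155 genes for low protein, 298 to 2021 for caloric restriction, 0 to 1956 between them, 0 to 1428 for the restricted diets, 2748 to 7236 between tissues and 0 to 1639 for the difference of diet effects. The highest diet counts, and r = 0.59 of the range 0.59 to 0.73 for the shared direction, came without low protein replicate 1. Leaving out a low protein replicate leaves 1 array of that diet in sperm, with the spread taken from other arrays. Counts of low protein comparisons from such fits describe that array and do not measure diet. The 2021 came without either low protein replicate, when fewer samples set the spread. For caloric restriction, leaving out control 1, 2 or 3 gave 487, 298 and 326. For the restricted diets, leaving out control 1, 2 or 3 or caloric restriction gave 0, and leaving out low protein replicate 2 gave 654; between the restricted diets the latter gave 317. The 2748 came without the low protein epididymis and the 7236 without low protein replicate 2. Lists called between the restricted diets ran from 6 to 13, the latter without low protein replicate 1. Medians turned without low protein replicate 2 for ribosomal proteins in low protein sperm (-0.85 to 0.0759) and in the difference of effects (-0.84 to 0.0463), and for the respiratory chain between the restricted diets (-0.44 to 0.0137). Between the restricted diets Smarcd3 ran from -1.74 to 0.43, turned without low protein replicate 2, and Ppard from -0.12 to 0.58, turned without replicate 1. Between tissues Smarcd3 ran from -1.12 to 0.35, turned without low protein replicate 2 or the low protein epididymis. Of other values of single genes and lists, 258 weaker and stronger ones arose under other settings and 272 on leaving out an array, with the direction kept. Signal over background was not analysed here.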

Other observations

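The list tests in this part were planned, and the genes named were picked among the largest changes of each list after the values were seen. Several lists not described above differed between sperm and epididymis. Of 74 respiratory chain genes 45 fell in sperm and 3 rose (46 and 3 adjusted over the list alone), with a list median of -0.78; Ndufa4 fell by 2.22 ± 0.32 (SE) while the testis form Cox8c rose by 1.84 ± 0.18. Of 39 proteasome genes 27 fell and 1 rose (27 and 1 adjusted over the list alone), where Psmd6 fell by 1.79 ± 0.21 and the germ cell subunit Psma8 rose by 1.74 ± 0.20. Of 21 piRNA pathway genes 9 rose and 2 fell (9 and 2 adjusted over the list alone), among the rises Mael at 2.76 ± 0.25. The piRNA list median was only 0.16, with 11 genes above 0 and 10 below. It was 0.0046 without the low protein epididymis array, 0.068 without low protein sperm replicate 2 and 0.088 without the control epididymis array. Camera called these lists at adjusted p = 1.54e-05, 6.8e-05 and 0.0234, and adjusted p = 0.433, 0.419 and 0.419 with an estimated correlation.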
